A study of Homo sapiens with 8 samples.

How the data were processed

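Jurkat cells, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line, were transduced with lentiviral hairpins and profiled on Exiqon LNA-probe miRNA arrays. Per the labels' protocols, medium was changed at 24 h and small RNA was isolated with a Roche kit at 48 h. Each of the 8 arrays carried the sample's RNA in Hy3 and a pool of all samples in Hy5, per the labels. The dyes ran the same way on every array, so a dye effect of a probe is shared by all arrays and drops out of differences between them.

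The deposited scanner files hold intensity values per spot, with signal, local background and quality flags, per the file headers. The scanner, the image program's settings and the slide numbers are not given in the sources used here. The authors' deposited table holds log2 ratios of Hy3 over Hy5, and its normalization and filter are not given in the sources used here. Its scale and direction were read from the values: regressed on the log2 ratios of bright spots, its slopes lay between 0.838 and 0.934. Column medians of the authors' deposited table were -0.04 and -0.07 for the GFP arrays, -0.01 and -0.015 for luciferase, -0.03 and -0.04 for TAL1 shRNA 1, and -0.01 and -0.03 for TAL1 shRNA 2. How the authors centred their values stays unknown.

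Spot intensities were corrected with normexp at an offset of 50 and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The offset shrinks fold changes of dim probes. Unflagged spots were averaged per probe, 4 per human probe, and the value tested was log2(Hy3/Hy5). A spot counted when its quality flag was 0 in both channels. What the other flag values stand for is not given in the sources used here.

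A human probe was tested when its Hy3 signal exceeded local background by 2 standard deviations on at least 4 arrays. That rule, fixed before the data were examined, passed 1236 of 1278 human probes, 857 of them named miRNAs and 379 vendor candidates called miRPlus, so it removed few dim probes. A stricter floor was added after the counts had been seen, at the median plus 3 median absolute deviations of viral miRNA probes. It was exceeded on at least 4 arrays by 251 of the tested probes. Per array, 229 to 271 human probes lay above it, and 757 to 1530 of 9360 spots were left out by flags, most on TAL1 shRNA 2 replicate 2. The number of arrays limits the precision.

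The 4 TAL1 hairpin arrays were set against the 4 control arrays with limma's lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. Comparisons of single constructs came from a fit with 4 construct means, whose spread is that between 2 duplicates. The labels call the duplicates biological, and the limma p-values of single probes measure the spread between these samples of 1 cell line. Shifts of 18 miRNA lists were tested with camera at a preset correlation of 0.01. Camera sets the changes of a list's members against those of the other probes, so its p-values rest on the spread over probes too. List members are probes, and both strands of a miRNA count, so a list can hold more members than miRNAs. The miRNAs named are those past the threshold, those with the smallest p until 20 were named, miR-223 in any case, up to 4 members of each list with the highest Hy3 signal, and up to 5 past the threshold with the largest change in each construct comparison.

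The fits were tested on simulated log ratios of 1228 probes with 200 changed. With the spread between duplicates alone, the arm fit recovered 98.1% of changes of 0.2 on the log2 scale, and 4.66% of its calls were false. With a spread between constructs added, it recovered 92.8% of those changes, and 19.7% of its calls were false, since duplicates of a construct are then not independent. The fit for TAL1 shRNA 2 against TAL1 shRNA 1 recovered 91.9% of simulated changes of 0.2. The simulated arm fits called 208 and 242 probes on average, against 1 in the data. The adjustment is more lenient where many probes change, so the recovered shares do not hold for the data. There miR-223 at -0.39 did not pass.

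Alternatives covered the background correction, the offset, the spot summary, the normalization, the Hy3 channel alone, the authors' values, the filter on dim probes, an intensity trend, array weights, the replicate number as a block, constructs as a random block or as means, and leaving out arrays or constructs. Quantile normalization of log ratios through average intensity leaves the ratios unchanged, so scaling was run in its place. The viral-probe floor, the authors' detected probes, the floor from the 95th percentile of empty and negative-control spots, quantile normalization of both channels and the construct number as a block were chosen after seeing the data. Slide and scan date could not be tested as batches, because the file headers give neither. Figures were drawn with matplotlib 3.10.9.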

Results

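Expression of miRNAs was compared between Jurkat cells that received hairpins against TAL1, a basic helix-loop-helix transcription factor active in many T-ALLs, and cells that received hairpins against GFP or luciferase. There were 4 constructs with 2 duplicates each, giving 4 TAL1 knockdown arrays and 4 control arrays. The arrays carry no probe for TAL1 mRNA, so its level could not be checked. Duplicates of a construct correlated at 0.925 to 0.969 across the 251 human probes above the viral-probe floor. Different constructs of one arm correlated at 0.692 to 0.772, and constructs of different arms at 0.662 to 0.889. Probes are not independent replicates. The median Hy3 signal of human probes over local background was 17.8 to 21.4 per array, below the viral-probe floor of 38.8 to 43.4. Their median Hy5 signal was -3.71 to 1.04 per array, so the reference lay near background for many of the ratios. The filter and the floor screened Hy3 only.

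The series asks which miRNAs depend on TAL1. miR-7, which targets EGFR in other cells, rose with TAL1 knockdown by 0.44 ± 0.05 on the log2 scale (SE, 4 against 4 arrays), a 1.36-fold increase with a limma adjusted p of 0.0147. Its log2 ratio was -0.15 ± 0.11 (SD, n = 4) in controls and 0.30 ± 0.06 in knockdown. miR-223, a myeloid miRNA and a described TAL1 target in T-ALL, was -0.39 ± 0.07 in the same contrast and did not pass, with a limma adjusted p of 0.126. All 4 knockdown arrays lay above all 4 controls for miR-7 and below them for miR-223, and an exact two-sided permutation test gave p = 0.0286 for each, the smallest that 4 against 4 arrays allow. It takes duplicates of a construct as independent, and miR-7 was picked by its limma p on these same arrays. With constructs as the units, 2 against 2, no exact two-sided permutation p can lie below 0.333.

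Only miR-7 passed among 1236 probes, and 116 had an unadjusted limma p under 0.05. Among the next miRNAs by p, none of which passed, were 3 sequences since assigned to tRNA fragments: miR-720 at 0.12 ± 0.02, miR-1308 at 0.14 ± 0.03 and miR-1274a at 0.19 ± 0.04. The candidate miRPlus-E1031 stood at 0.27 ± 0.06, miR-542-5p at -0.16 ± 0.03, miR-492 at -0.18 ± 0.04, miR-29c at -0.14 ± 0.04 and miR-26a at -0.11 ± 0.03. miR-1261 and the candidate miRPlus-E1038 stood at 0.12 each. The signal of miR-105, miR-1203, miR-1255b, miR-640, miRPlus-F1056, miRPlus-F1014, miRPlus-F1213 and miRPlus-F1072 exceeded the viral-probe floor on 0 of 8 arrays, so no change is given for them, and miR-542-5p exceeded it on 3 arrays and miR-492 on 5. The arms separated completely for 82 of 1236 probes, or 6.63%, against 2.86% by chance if the 8 arrays were independent. The construct means of the arms separated for 424 of 1236, or 34.3%, against 33.3% by chance if the constructs were independent. On that assumption little excess is left once constructs are the units. However, luciferase minus GFP and TAL1 shRNA 2 minus TAL1 shRNA 1 correlated at 0.415 across 1228 probes. The constructs are thus not independent, and 33.3% is no firm baseline. The miR-7 call was lost without TAL1 shRNA 1 replicate 2 (0.46, limma adjusted p = 0.0570), TAL1 shRNA 2 replicate 1 (0.43, adjusted p = 0.0775), TAL1 shRNA 2 replicate 2 (0.43, adjusted p = 0.0959) or both arrays of TAL1 shRNA 2 (0.39, adjusted p = 0.309). It was also lost with median centring (0.47, limma adjusted p = 0.553) and in Hy3 alone (0.39, adjusted p = 0.997). With constructs in place of arrays as the units it was lost as well (0.44, adjusted p = 0.972). The change kept its direction, which taking constructs as the units could not alter. Without GFP replicate 1, 3 probes passed, miR-223 among them (limma adjusted p = 0.0390). Set against the spread between duplicates alone, in a contrast of the 4 construct means, 27 probes passed, with limma adjusted p of 2.93e-06 for miR-7 and 4.00e-05 for miR-223; over all alternatives these p ranged up to 0.997 for both.

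**Figure D1:**
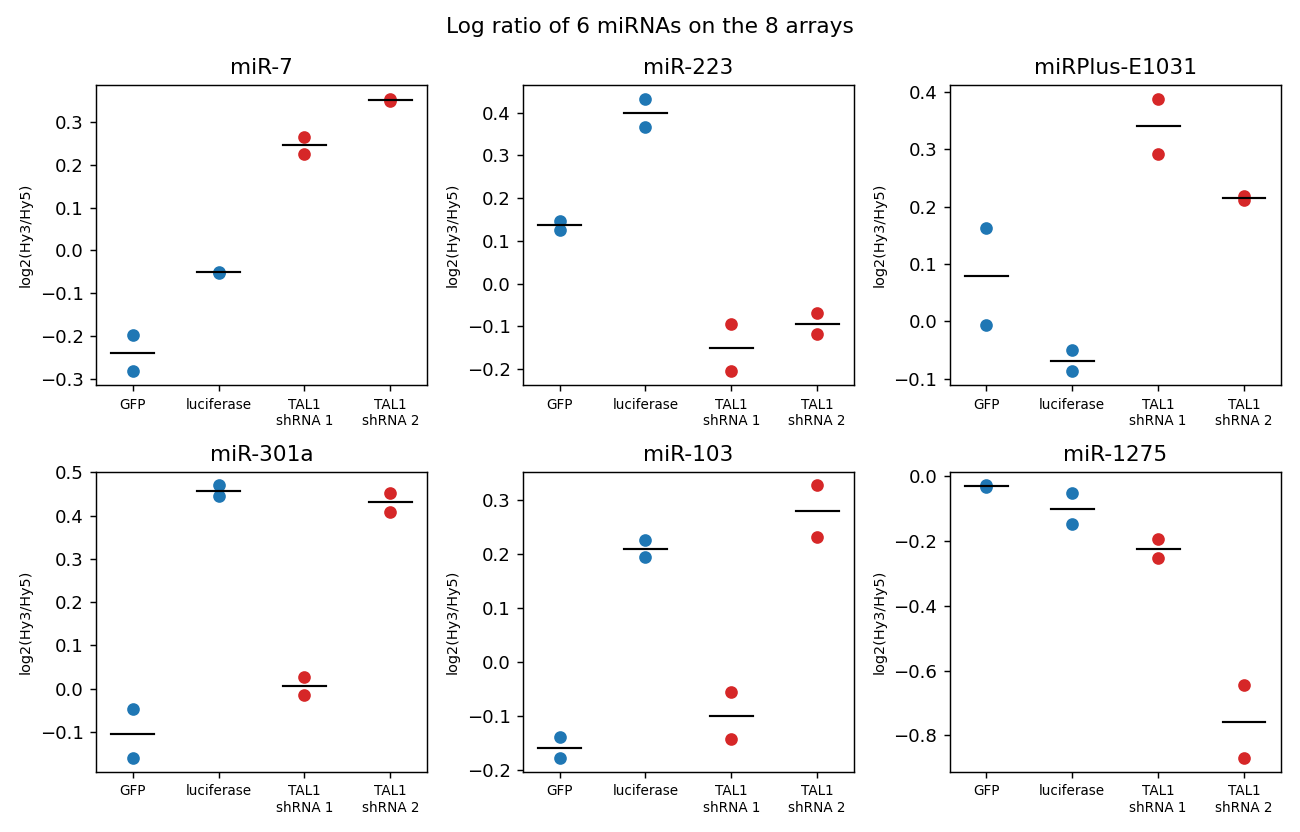
Log2 ratio of sample over pooled reference (Hy3/Hy5, vertical axis) for 6 miRNAs on each of the 8 arrays, by construct; points are arrays, bars the mean of 2 duplicates, blue controls and red TAL1 hairpins. miR-7 and miR-223 separate by arm, while miR-301a and miR-103 are higher with luciferase and TAL1 shRNA 2 than with GFP and TAL1 shRNA 1.

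Of 18 miRNA lists, 2 shifted down with TAL1 knockdown by camera in limma. The suppressor miRNAs of T-ALL fell, with 14 of 17 tested members lower, both strands of a miRNA counted, and a mean of -0.04. The camera adjusted p was 0.0141 at the preset correlation and 0.588 with an estimated correlation. None of the 17 passed over all probes or adjusted over the list alone. Among its brightest members miR-29a stood at -0.09 ± 0.03, miR-29b at -0.10 ± 0.09, miR-29c at -0.14 ± 0.04 and miR-150 at -0.04 ± 0.05, and only 4 members lay above the viral-probe floor. The list's mean was higher with luciferase than with GFP by 0.05. The miR-181 family, which tunes T-cell receptor signalling, fell with 6 of 7 members lower and a mean of -0.06 (limma camera adjusted p = 0.0436, adjusted p = 0.588 with an estimated correlation); miR-181a was -0.09 ± 0.04, miR-181b -0.10 ± 0.03 and miR-181d -0.13 ± 0.06, none past the threshold. The family's mean was higher with luciferase than with GFP by 0.04, and the log2 ratio of miR-181d was -0.08 with GFP, -0.10 with each TAL1 hairpin and 0.14 with luciferase. By fry, which tests a common direction, the adjusted p was 0.385 for both lists. No list passed without luciferase replicate 1, luciferase replicate 2 or TAL1 shRNA 1 replicate 2 (0 lists each, camera), 1 passed without TAL1 shRNA 2 replicate 1, and 0 passed with median centring. The suppressor list's mean ranged from -0.01 without both luciferase arrays (limma camera adjusted p = 0.526) to -0.10 in the authors' values, and the miR-181 mean from -0.02 with median centring (0.743) to -0.14 in the authors' values.

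In the TAL1-linked list miR-223 passed when adjusted over the list alone, and in the oncogenic list of T-ALL miR-223 and miR-26a did, while no member of the 18 lists passed over all probes. By fry's test of change in either direction these 2 lists passed, with adjusted p of 0.00498 and 0.00187. Both lists hold miR-223, which may have been picked on these samples, so the 2 results are not separate evidence. The TAL1-linked list may have been drawn in part from knockdown experiments of this kind, so it is not independent evidence. Only 2 of 10 TAL1-linked and 6 of 13 oncogenic members lay above the viral-probe floor. Of 30 members of the miR-17-92 cluster and its paralogs, which drive proliferation in lymphoid cells, 19 were higher; miR-17 stood at 0.12 ± 0.07, miR-20a at 0.14 ± 0.05, miR-19a at 0.04 ± 0.03 and miR-19b at -0.05 ± 0.03. In the let-7 family 12 of 19 were higher, with let-7a at -0.06 ± 0.03 and let-7b at 0.02 ± 0.02. Camera gave adjusted p of 0.646 or more in limma for the remaining 16 lists, these 4 included. Among the others, higher members numbered 7 of 14 in the miR-15/16 family, 6 of 10 in the miR-30 family, 5 of 10 in the miR-23/27/24 clusters and 3 of 4 in the cluster of miR-221 and miR-222. They numbered 7 of 12 activation and inflammation miRNAs, 2 of 4 erythroid, 2 of 9 p53-linked and 3 of 8 HOX cluster miRNAs, and 24 of 47 miRNAs of the imprinted cluster at 14q32. Of miRNAs of other cell types, 3 of 12 epithelial, 5 of 11 muscle, liver and neural, and 8 of 18 mesenchymal and endothelial ones were higher. Above the viral-probe floor lay 4 of 12 activation and inflammation, 0 of 4 erythroid, 1 of 9 p53-linked, 1 of 8 HOX cluster and 3 of 47 14q32 members. So did 1 of 12 epithelial, 2 of 11 muscle, liver and neural, and 0 of 18 mesenchymal and endothelial ones. Most of these directions are thus those of dim probes.

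TAL1 shRNA 1 was set against both controls to ask what this hairpin does by itself. miR-223 fell by 0.42 ± 0.03 (SE, 2 against 4 arrays, limma adjusted p = 0.000142), miR-7 rose by 0.39 ± 0.03 (7.19e-05) and miRPlus-E1031 rose by 0.34 ± 0.04 (0.00541). miR-185* rose by 0.29 ± 0.04 and miR-183 fell by 0.21 ± 0.03. In all 14 probes passed, 6 up and 8 down. Against GFP alone 5 passed and against luciferase alone 63, of which 51 were down. Of the 14, 3 also passed in the same direction against each control alone, namely miR-7, miR-223 and miR-185*; miR-183 (-0.10 ± 0.03, limma adjusted p = 0.247) and miRPlus-E1031 (0.26 ± 0.05, limma adjusted p = 0.0613) did not pass against GFP. The count was 7 and 8 without GFP replicates 1 and 2, 7 and 24 without luciferase replicates 1 and 2, 9 and 6 without TAL1 shRNA 1 replicates 1 and 2, and 8 without either TAL1 shRNA 2 array.

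TAL1 shRNA 2 moved more probes than TAL1 shRNA 1 against GFP alone (128 against 5) and fewer against luciferase alone (41 against 63). Against both controls TAL1 shRNA 2 moved more, 99 against 14. miR-1275 fell by 0.69 ± 0.05 (limma adjusted p = 8.12e-05), miR-1908 fell by 0.54 ± 0.05 and miR-1290 fell by 0.50 ± 0.06. miR-7 rose by 0.50 ± 0.03 (7.06e-06) and miR-223 fell by 0.36 ± 0.03 (0.000274). Of the miR-17-92 members 7 rose, miR-17 by 0.24 ± 0.02 and miR-20a by 0.23 ± 0.03 among them, miR-221 rose by 0.13 ± 0.02 and miR-222 by 0.10 ± 0.02, and 3 members of the miR-181 family fell. Against luciferase alone miR-221 (0.04 ± 0.03) and miR-222 (0.02 ± 0.03) did not pass, with limma adjusted p of 0.505 and 0.841, so both calls rest on the GFP arrays. Of the 7 miR-17-92 members 3 passed against each control alone, miR-17 and miR-20a among them, and of the 3 miR-181 members 0 did: miR-181b and miR-181d did not pass against GFP (limma adjusted p = 0.421 and 0.839), nor miR-181a* against luciferase (0.0801). In all 99 passed, 48 up and 51 down, 128 against GFP alone (84 up, 44 down) and 41 against luciferase alone (17 up, 24 down); 26 of the 99 passed in the same direction against each control alone, miR-7, miR-223, miR-1275, miR-1908 and miR-1290 among them. The count was 65 and 53 without GFP replicates 1 and 2, and 42 and 39 without TAL1 shRNA 2 replicates 1 and 2. Of 5 probes that passed with both TAL1 hairpins, miR-7, miR-223 and miRPlus-E1031 moved the same way and miR-183 and miR-301a moved in opposite directions. That is 2 shared up and 1 shared down, while simulated unchanged hairpins that share the controls gave 0 and 0 with the spread between duplicates alone, and 13.6 and 13.4 with a spread between constructs too. The changes of both hairpins correlated at 0.184 across 251 probes, with a covariance of 0.00197, against 0.341 and 0.000579 in the first simulation and 0.321 and 0.00476 in the second. The first simulation called at most 0.06 probes per hairpin and direction on average, so its overlap of 0 was fixed in advance. The second called 44.7 up and 45.1 down for TAL1 shRNA 1, where the data gave 6 and 8. The simulations also draw constructs independently, which these constructs are not, so they set no bound for these samples. With the controls split, the correlation was 0.205 (TAL1 shRNA 1 against GFP, TAL1 shRNA 2 against luciferase) or -0.369 the other way round.

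TAL1 shRNA 2 against TAL1 shRNA 1 tests whether the hairpins differ. With shRNA 2 miR-1290 fell by 0.55 ± 0.07, miR-1275 fell by 0.53 ± 0.06 and miR-1908 fell by 0.52 ± 0.06, while miR-301a rose by 0.42 ± 0.04 and miR-183 by 0.40 ± 0.03 (limma adjusted p = 0.000286 for miR-183). Of the miR-17-92 members 10 rose, and 6 rose between the controls. In all 94 passed, 56 up and 38 down, and 60 and 52 passed without TAL1 shRNA 2 replicates 1 and 2. miR-7 (0.11 ± 0.03) and miR-223 (0.06 ± 0.04) did not pass here, with limma adjusted p of 0.0790 and 0.580.

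Luciferase against GFP compares hairpins with no human target. miR-301a rose with luciferase by 0.56 ± 0.04 and miR-301b, of the same family, by 0.44 ± 0.03 (limma adjusted p = 4.56e-05 for both), miR-342-3p by 0.38 ± 0.03 and miR-103 by 0.37 ± 0.04, and miR-487b fell by 0.34 ± 0.07. Of the miR-17-92 members 6 rose, with a mean of 0.06 over all 30. miR-223 also rose, by 0.26 ± 0.04, and miR-7 by 0.19 ± 0.03. In all 83 passed, 61 up and 22 down, beside the 94 between the TAL1 hairpins, and 54 and 38 passed without GFP replicates 1 and 2. The median absolute difference was 0.08 between the controls, 0.08 between the TAL1 hairpins and 0.04 between the arms, beside a median SD of 0.03 between duplicates. In limma none of the 4 construct comparisons gave a probe past the threshold with median centring or in Hy3 alone.

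**Figure D2:**
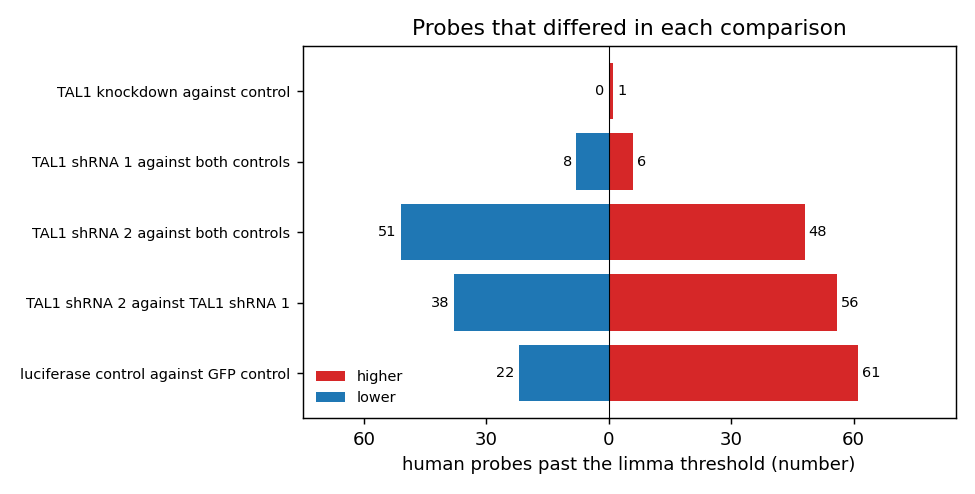
Number of human probes past the limma threshold (horizontal axis), higher to the right in red and lower to the left in blue, for 5 comparisons. The arms differ in 1 probe, the TAL1 hairpins in 94 and the controls in 83. The arm fit counts the spread between constructs as error, while the other comparisons count only that between duplicates. With the spread between duplicates alone the arms differ in 27 probes.

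**Figure D3:**
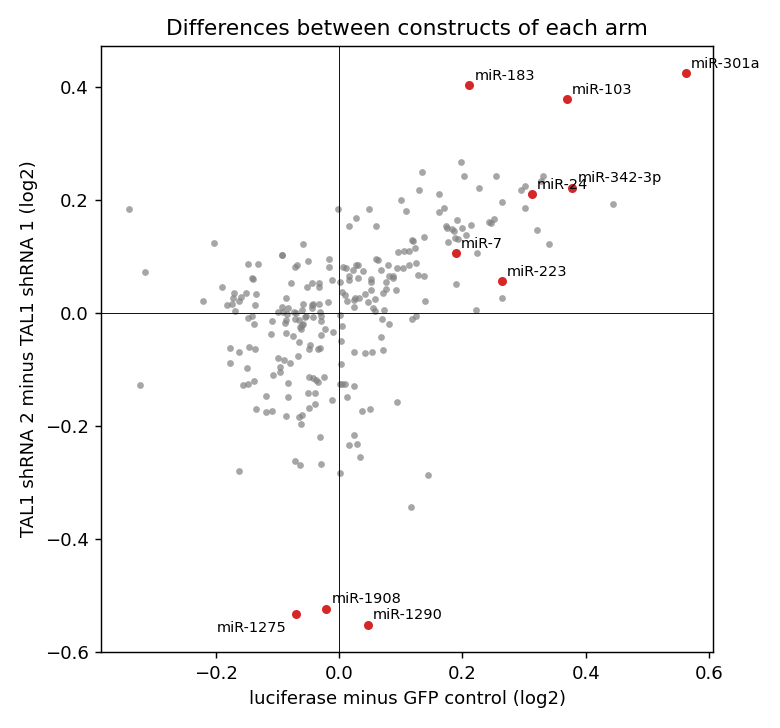
Difference of luciferase from GFP (horizontal axis, log2) against that of TAL1 shRNA 2 from TAL1 shRNA 1 (vertical axis, log2) for the 251 probes above the viral-probe floor; named miRNAs are in red. miR-301a and miR-103 are high on both axes.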

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

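Except for those on the Hy5 channel, the tests weighing explanations here were chosen after the results were seen, and so was the rule that a Hy5 value within 2 standard errors of 0 decides nothing.

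Differences between constructs: 94 probes separated the TAL1 hairpins and 83 the controls. Between the TAL1 hairpins the Hy5 difference followed the log ratio difference with a slope of 0.690 ± 0.0855 over the 94 probes. The SE is over probes of the same arrays, which are not independent. Noise in the shared reference, which needs a slope below 0, is thus argued against for these 94 probes. This slope was not taken for the 83 probes between the controls. Hy5 held the same pool on every array, so this Hy5 difference does not reflect a difference in the pool. Its cause was not tested. Viral probes were taken to have no target in these cells, which was not checked. Between the TAL1 hairpins 5 of 12 above their floor passed (41.7%, exact 95% interval 15.2 to 72.3%). Of human probes 33.1% did, and 34.8% of those of like signal. Between the controls 0 of 12 viral probes passed (at most 26.5%), against 28.9% of human probes of like signal. However, 6 of these 12 had an unadjusted limma p under 0.05, and viral probes are adjusted over another set of probes. Non-specific signal thus stays open for both. The controls gave 0.883 of the calls that the TAL1 hairpins gave, which met the bound for duplicates having been handled together. That bound was set after these same counts were seen, so it cannot decide whether duplicates of a construct were handled together. Off-target effects of a hairpin, a biological explanation, were not tested and stay open.

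The opposite moves of miR-7 and miR-223: the gap between the nearest construct means of the arms was at least 4.66 times the duplicates' SD for both. All 4 pairs of a TAL1 hairpin with a control passed in limma (adjusted p at most 0.000458 for miR-7 and 0.0107 for miR-223). In these arrays the difference is thus not carried by a single construct. Both miRNAs had the smallest limma p between the arms, so such gaps were partly selected for. The pairs share constructs, and their error is the spread between duplicates alone. Variation between constructs stays open. The gap of miR-223 (0.23) is below its difference between the controls (0.26), while that of miR-7 (0.30) is above its largest difference within an arm (0.19). The reference channel stays open for both, since the Hy5 difference, turned in sign, came to 0.319 ± 0.418 of the log ratio difference for miR-223, and the Hy5 difference of miR-7 was 0.02 ± 0.17 beside its change of 0.44. Reduced TAL1 is a hypothesis for both, tested on the same data. Chance is not excluded for the count: 3 of 35 splits of the 8 arrays, the arms included, gave at least 1 probe. Most splits part duplicates of a construct, which counts construct differences as error, so this share is no firm measure of chance. Splits that keep duplicates together gave 0 probes, 1 for the arms and 80 for the highest other. That split parts the constructs numbered 1 from those numbered 2, which points to a structure of the samples; with this number as a block 17 probes passed, both miRNAs among them, and with 2 against 2 construct means 0 passed.

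The 6 tRNA-derived sequences were higher with knockdown by a mean of 0.12 (median 0.13), none past the limma threshold between the arms, and they were grouped after their values were seen; miR-720, miR-1274a, miR-1274b and miR-1308 had an unadjusted p under 0.05 and passed in the contrast of construct means. Small nuclear, nucleolar and ribosomal RNA probes had a median of -0.0165 ± 0.0112 (SE over 23 probes of the same arrays, which are not independent). These probes did not rise beside the tRNA-derived ones. Loess centres each array, so a rise of all small RNAs could not be seen and stays open. The gap between the nearest construct means was 2.19 times the duplicates' SD, under the 2.78 needed with so few arrays, so whether a single construct carries it stays open. The mean Hy5 difference, turned in sign, was 0.713 ± 0.604 of the log ratio difference; it lies above the bound set beforehand, which alone would have favoured this explanation, but within 2 standard errors of 0, so the reference channel cannot be told apart from a change in the samples. A biological change stays open as untested.

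Of the 2 lists shifted, chance is not excluded either: 6 of 35 splits, the arms included, shifted at least 2 lists. The highest other split shifted 3. Splits that keep duplicates together shifted 2 (the arms), 2 and 0 lists, so 6 of 35 is no firm measure of chance.

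Among 95 named miRNAs, 24 differed between the TAL1 hairpins in limma. With shRNA 2, miR-301a was higher by 0.42, miR-183 by 0.40, miR-103 by 0.38, miR-17 by 0.24, miR-342-3p by 0.22, miR-24 by 0.21, miR-301b by 0.19, miR-222 by 0.19, miR-20a by 0.18, miR-23b by 0.17, miR-21 by 0.15, miR-142-3p by 0.15, miR-15b by 0.14, miR-221 by 0.13, let-7i by 0.13, miR-9* by 0.13 and miR-126 by 0.11. The difference was -0.55 for miR-1290, -0.53 for miR-1275, -0.52 for miR-1908, -0.34 for miR-185*, -0.20 for miR-494, -0.17 for miR-150 and -0.12 for miR-181a*.

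One array stood apart from the other 3 of its arm in 7 of 190 tests, and chance gives about 1 in 20 for independent arrays. Each arm is 2 constructs with 2 close duplicates, so that rate does not hold here. The gap over the range was 0.861 for miR-92a (luciferase replicate 2), 0.850 for let-7b (luciferase replicate 1), 0.856 for miR-181a (TAL1 shRNA 2 replicate 1), 0.857 for miR-24-1* (TAL1 shRNA 1 replicate 1), 0.889 for miR-221* (luciferase replicate 1), 0.924 for miR-215 (GFP replicate 2) and 0.95 for miR-485-3p (TAL1 shRNA 1 replicate 2).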

How the results depend on the processing

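The viral-probe floor, the authors' detected probes, the floor from empty and negative-control spots, quantile normalization and the construct number block were chosen after seeing the data, the viral-probe floor and the authors' detected probes after miR-223 had missed the threshold. For TAL1 knockdown against control the count of 1 became 0 with median centring, Hy3 alone, 2 against 2 construct means or without both arrays of TAL1 shRNA 2, 2 with the authors' deposited values, the viral-probe floor or the authors' detected probes, 4 without both arrays of GFP, 10 without both of TAL1 shRNA 1, 17 with the construct number block and 27 in the contrast of construct means. Over 32 alternatives miR-7 was higher in each and passed in 25 (limma adjusted p from 2.93e-06 to 0.997). In the same alternatives miR-223 was lower in each and passed in 7 (4.00e-05 to 0.997). Alternatives that change only the filter, the trend, a block or the units leave the differences at 0.44 and -0.39, so their direction was fixed in advance. The others reuse the same arrays, so the shared direction is no separate evidence. For TAL1 shRNA 1 against both controls the 14 probes became 2 with offset 10, 0 with median centring or Hy3 alone, 1 with quantile normalization, 5 against GFP alone and 63 against luciferase alone. For TAL1 shRNA 2 against both controls the 99 became 36 with offset 10 (13 up, 23 down), 0 with median centring or Hy3 alone, 65 with scaling, 3 with quantile normalization and 41 against luciferase alone. For TAL1 shRNA 2 against TAL1 shRNA 1 the 94 became 42 with offset 10, 0 with median centring or Hy3 alone and 1 with quantile normalization, and the authors' deposited values gave 45 up and 45 down. For luciferase control against GFP control the 83 became 46 with offset 10 (41 up, 5 down), 0 with median centring or Hy3 alone and 8 with quantile normalization, and miR-487b turned from -0.34 to 0.22 in Hy3 alone, not past the threshold there. For miRNA lists shifted by TAL1 knockdown the 2 became 1 with offset 10, scaling, Hy3 alone, construct means, or without both arrays of TAL1 shRNA 2, 1 shifted up without both arrays of TAL1 shRNA 1, and 0 with median centring, quantile normalization, without both arrays of luciferase, with an estimated correlation or by fry. Leaving out 1 array at a time gave 0 to 3 probes for the arms, 6 to 24 for TAL1 shRNA 1, 39 to 124 for TAL1 shRNA 2, 52 to 90 between the TAL1 hairpins, 38 to 97 between the controls and 0 to 2 lists; where 1 array of a construct was left, it is assumed to vary like the others. The arms gave 0 without TAL1 shRNA 1 replicate 2 or either TAL1 shRNA 2 array and 3 without GFP replicate 1; TAL1 shRNA 1 gave 7, 8, 7, 24, 9, 6, 8 and 8 without GFP, luciferase, TAL1 shRNA 1 and TAL1 shRNA 2 replicates 1 and 2 in turn. TAL1 shRNA 2 gave 65 and 53 without GFP replicates 1 and 2 and 42 and 39 without its own; the TAL1 hairpins gave 60 and 52 without TAL1 shRNA 2 replicates 1 and 2, and the controls 54 and 38 without GFP replicates 1 and 2. The lists were 0 without either luciferase array or TAL1 shRNA 1 replicate 2 and 1 without TAL1 shRNA 2 replicate 1. The cause was not tested for any of these. With the replicate number as a block, 1 probe passed between the arms, 12, 74, 85 and 75 in the construct comparisons and 2 lists; deviations of duplicates with the same number correlated at -0.213 to 0.228 across constructs, with no common sign, which gives no consistent pairing. Of 3680 values of single miRNAs and lists, 3547 kept their side of the threshold, 93 fell below it, 39 came past it and 1 reversed; 250 changed sign without passing in either setting. A block for slide or scan date was not run because the headers give neither, and the random block was not run for the lists because camera takes none. Signal over background limits the dim probes: 251 of 1236 lay above the viral-probe floor on at least 4 arrays.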

Other observations

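With the number that the labels give to each construct as a block, an alternative chosen after seeing the data, 17 probes passed between the arms in limma, 9 up and 8 down. They held miR-17, miR-18a and miR-20a of the miR-17-92 cluster (0.12, 0.13 and 0.14), the hypoxia miRNA miR-210 (-0.29), miR-29c (-0.14), miR-181a* (-0.12) and miR-378 (0.10), beside miR-7 and miR-223 (adjusted p = 0.00180). The spread in this fit and in the contrast of construct means, where all 17 also passed, comes mostly or wholly from duplicates; with 2 against 2 construct means as the units 0 passed in limma. miR-210, miR-18a and miR-378 are named here after their values were seen.

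The differences between constructs share an axis. Luciferase minus GFP and TAL1 shRNA 2 minus TAL1 shRNA 1 come from separate arrays, and they correlated at 0.510 across 251 probes (Spearman 0.540), 0.490 in the authors' deposited values, 0.467 in Hy3 alone and -0.080 in Hy5 alone. Splitting the arrays by construct number gave 80 probes in limma, against 1 for the arms. The hypothesis, formed and tested on the same data, is that constructs numbered 1 and those numbered 2 may have been handled in separate batches; the correlation of 0.510 fits it, but the labels name no batch, and a shared property of these hairpins was not tested.

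Among 99 viral probes 0 passed between the arms in limma, with 9 at an unadjusted p under 0.05, 6 passed between the TAL1 hairpins, all lower with shRNA 2, and 0 between the controls, with 15 there at an unadjusted p under 0.05. Among 23 small nuclear, nucleolar and ribosomal RNA probes 8 passed between the controls and 0 between the TAL1 hairpins, with 2 there at an unadjusted p under 0.05.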
